A study of Mus musculus with 6 samples.

How the data were processed

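The series measured gene expression in single cells of the mouse small-intestinal epithelium with 10x 3' libraries. It held 6 libraries of C57BL/6J mice aged 8 weeks, 3 titled wild-type and 3 titled Itgb7 KO, each group numbered 1 to 3. The labels do not say whether each library came from 1 animal or several, so p-values measure only the spread between these libraries, which may be in part technical.

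The deposited values are whole-number UMI counts per gene and barcode (a UMI marks 1 captured RNA molecule), made by the authors and not normalized. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Cell Ranger 2.1.1 and Seurat (version not given in the sources used here) were used with the mm10 genome build. The deposited matrices held 27998 genes and 26153 barcodes. Their smallest UMI total per barcode differed between libraries, from 1417 to 13621, so the barcodes had been chosen with different lower limits before deposit. Positions of genes were taken by gene identifier from GENCODE M21, an annotation of the same mouse build, which held 27645 of the 27998 identifiers (98.7%).

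Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 25% of UMIs from mitochondrially encoded genes. Of all barcodes, 3 failed the first limit, 0 the second and 107 the last. Doublets, droplets with more than 1 cell, were scored per library with the Scrublet method of scanpy. Its automatic threshold marked under 0.5% of the barcodes in 5 of the 6 libraries, so the rule set in advance was used, which removed the highest-scoring 0.8% per 1000 barcodes of the library, 975 in all. The 25070 cells that remained (95.9% of the barcodes) were scaled to 10000 UMIs, and 2000 variable genes and 30 principal components were corrected for library with an own implementation of the Harmony type. Leiden clustering at resolution 1.5 on 15 neighbours gave 24 clusters. Genotype was not given to the clustering.

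A cluster was called X-like when markers of that class, fixed in advance, led those of every other class among its 10 genes with the highest fold and at least 3 lay among its 50. No cluster had more markers of another class than of its own among the first 10. Cluster 16 of the mature enterocyte-like cells tied with lower-villus enterocyte markers and cluster 18 of the stem-like cells tied with transit-amplifying markers. Cluster 15 of the transit-amplifying-like cells held 4 markers of its own and 3 of stem cells. Cluster 1, with 1805 of the lower-villus enterocyte-like cells, held 3 markers of its own and 2 of mature enterocytes. Of its first 10 genes 4, such as Fabp6 and Slc51b, were on the distal intestine list. The lower-villus enterocyte-like class may thus mix position on the villus with intestinal region. Stem-like cluster 8 was led by S-phase genes such as Ung, Hells and Uhrf1. Goblet-like cluster 0, with 752 cells, was led by Atoh1 and held Spdef and Dll1 among its first 10 genes. These genes are on the list of secretory fate genes, so the goblet-like class may include secretory progenitors. Cluster 21, with 615 cells, a median of 14.0% mitochondrial UMIs and no marker among its first 10 genes, stayed unnamed. It made up 1.84% ± 1.16 (SD, n = 3) of kept wild-type cells and 2.86% ± 0.81 (SD, n = 3) of those labelled Itgb7 KO (exact 2-sided permutation test, p = 0.3). The other 24455 cells formed 8 epithelial classes. No cluster was T-cell-like, so the gene tests planned for such cells could not be made, and tuft-like cells were too few for a gene test, which needed 20 cells of a class in a library.

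Cells are not replicates, so UMI counts were summed per library and class. These sums were tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, genotype as the only term) and Benjamini-Hochberg adjustment at 0.05. Gene expression is given as counts per 1000000 UMIs (CPM) of the class, as mean ± SD over libraries, and fold changes as log2 of libraries labelled Itgb7 KO over wild-type with the standard error (SE). Class shares were tested with the same edgeR test on numbers of cells, adjusted over 8 classes, beside exact 2-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1. From 38 gene lists fixed in advance, those with at least 3 tested members in a class were tested with limma's camera (inter-gene correlation preset at 0.01, prior count 2), adjusted over lists and classes. Camera compares a list's genes with all others. Camera with an estimated correlation and fry, whose p tests whether a list's genes move on balance one way without comparing them with other genes, were run as alternatives.

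Genes were named by a rule written before the data were examined, as were the groups, tests, filters, markers and lists. It took Itgb7, Itgae, Itga4, Itgb1 and Cdh1, and up to 4 called members of each list in each class. It also took up to 8 genes called higher and 8 lower in a class with a mean log2 CPM of at least 5 and no overlap between the groups. Further, it took Lgr5, Axin2, Ascl2, Sox9, Hes1, Atoh1 and Dll1 in stem-like and transit-amplifying-like cells whatever their p. In a class with fewer than 5 genes passing it took the 4 list members with the smallest unadjusted p, given as values. Members of gene families whose copies share sequence (alpha-defensins, immunoglobulins, T cell receptor variable genes, histones, Sprr2 genes) were to be reported as uncertain. After the data were seen, Lyz2, Cst3 and Itgae were left out of the pooled markers of immune cells, because epithelium expresses them or a close copy.

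The groups share the numbers 1 to 3 in the titles. Over genes, the deviations from the group means correlated between libraries of the same number with 0.66 for number 1, 0.28 for number 2 and 0.28 for number 3, all over the limit of 0.1 set for treating the numbers as pairs. Wild-type replicate 2, however, correlated more with the library labelled Itgb7 KO replicate 3 (0.48), and wild-type replicate 3 nearly as much with replicate 2 of that group (0.26). Deviations cancel within each group, so the match of number 1 alone raises the correlations among the remaining libraries. For numbers 2 and 3 the check therefore cannot decide on pairs. The pairing comes from the numbers in the titles and, for number 1 only, from this check, not from a stated litter or day. Replicate 1 of both groups also had the highest UMI minima. The fit without the numbers as a block was fixed as the main one.

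Alternatives set in advance were DESeq2, DESeq2's size factors in edgeR, no filter on low counts, the replicate number as a block, blocks from the serial numbers in the deposited file names and leaving out each library in turn. Among those serial blocks wild-type replicate 3 was alone in its block, so it added nothing to the genotype difference in that fit. Also set in advance were 1 UMI minimum of 13621 for all libraries, at most 10% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.8 and 2.5, no correction for library, all kept cells as denominator and cells thinned to 3000 UMIs, which left out 437 cells. Chosen after the data were seen were 2 groups of serial numbers as a block, the 4 libraries of replicates 2 and 3 alone, UMI minima matched between the groups, and all alternatives of the interferon and MHC lists. That result was itself singled out after the list tests were seen. A value was called the same under an alternative when it kept its side of the threshold, or, where neither fit passed, when it moved by less than its standard error. For a list this was the SD of its members divided by the square root of their number, a choice made after the data were seen.

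Each test was tried on simulated counts drawn from the real means and library sizes with 200 changed genes. In stem-like cells (10784 genes) 55% of 2-fold and 94% of 4-fold changes were recovered. The matching percentages were 50 and 91 in transit-amplifying-like cells (11830 genes), 56 and 91 in lower-villus enterocyte-like cells (9974 genes), 42 and 92 in mature enterocyte-like cells (10751 genes), 50 and 90 in goblet-like cells (11091 genes), 16 and 84 in Paneth-like cells (2564 genes), 8 and 74 in enteroendocrine-like cells (8427 genes) and 34 and 91 in all epithelial cells (13540 genes). In each of these groups 2 to 12 unchanged genes were called too. The simulated genes varied independently and held no structure by serial number, so the percentages may overstate recovery in the real data. With the interferon response list raised 2-fold, camera at the preset correlation called that list in every group (adjusted p up to 0.000152). It also called 1 unchanged list in each of stem-like, transit-amplifying-like, lower-villus enterocyte-like and all epithelial cells. A doubled share of enteroendocrine-like cells was called in 19 of 50 simulations, with 6 calls of other classes. Analyses were run in Python 3.11.15 (scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0).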

Results

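Single-cell transcriptomes were collected from the small-intestinal epithelium of wild-type C57BL/6J mice and of mice labelled Itgb7 KO, with 3 libraries in each group. Itgb7 encodes the β7 integrin subunit, which pairs with the αE subunit (Itgae) to bind E-cadherin (Cdh1) on epithelial cells and with the α4 subunit (Itga4) on gut-homing lymphocytes. Per the series title, the study asked whether T cells that carry this integrin influence the fate choice of intestinal stem cells. Wild-type replicates 1, 2 and 3 held 2773, 5058 and 5145 barcodes. Their UMIs numbered 76133693, 63316811 and 63647862 in all, with medians of 22384, 11920.5 and 12103 UMIs per barcode. The libraries labelled Itgb7 KO held 2797, 5738 and 4642 barcodes. These gave 62224718, 57949476 and 28475253 UMIs, with medians of 19529, 9284 and 6079.5 UMIs per barcode.

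The Itgb7 transcript (ENSMUSG00000001281, chromosome 15, positions 102215995 to 102231944, minus strand) was rare in every library and was more frequent in the libraries labelled Itgb7 KO. Over all barcodes, wild-type libraries held 3, 8 and 2 Itgb7 UMIs and libraries labelled Itgb7 KO held 18, 33 and 12. These made 0.000657 ± 0.000527 (SD, n = 3) and 0.00427 ± 0.0014 (SD, n = 3) per 10000 UMIs. The groups did not overlap (exact 2-sided permutation test, p = 0.1, the smallest that 3 against 3 libraries allow). In all kept cells the log2 fold change was 3.14 ± 0.49 (SE), which edgeR did not call (adjusted p = 0.583) and DESeq2 did (3.22, adjusted p = 0.0229). Of the Itgb7 UMIs in kept cells labelled Itgb7 KO, 23 lay in transit-amplifying-like cells and 18 in mature enterocyte-like cells. The labels do not say which part of the gene was deleted. A 3' tag can lie outside it, so these UMIs neither check nor contradict the labels. Because the direction goes against the label, the group is called "libraries labelled Itgb7 KO" here, and every direction below rests on those labels.

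Transcripts of the partner integrins and of their epithelial ligand were not called different in all kept cells. Itgae, at 25, 24 and 26 UMIs in wild-type libraries and 17, 9 and 11 in those labelled Itgb7 KO, had a log2 fold change of −0.51 ± 0.40 (SE, edgeR adjusted p = 0.953). Itga4, at 1, 2 and 3 against 10, 5 and 9 UMIs, was too rare to be tested. Itgb1, the β1 subunit, had a log2 fold change of 0.09 ± 0.12 and Cdh1 of −0.16 ± 0.19 (SE, both with edgeR adjusted p = 0.953). T cells themselves were nearly absent from the data. Only 1 of the 26153 barcodes, in wild-type replicate 1, held at least 3 of 18 T cell markers. T cell markers made 2.90 ± 1.11 CPM (counts per 1000000 UMIs; SD, n = 3) in wild-type libraries and 1.55 ± 0.32 (SD, n = 3) in those labelled Itgb7 KO.

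The composition of the epithelium was examined next, to ask whether the absorptive and secretory classes that stem cells give rise to took different shares. Stem-like cells made up 13.6% ± 2.59 (SD, n = 3) of wild-type and 13.8% ± 2.12 (SD, n = 3) of epithelial cells labelled Itgb7 KO. Transit-amplifying-like cells, the dividing progenitors, made up 30.1% ± 3.28 and 29.8% ± 2.28 (SD, n = 3 each). The absorptive classes also lay close together. Lower-villus enterocyte-like cells made up 10.5% ± 0.52 and 10.99% ± 2.05, and mature enterocyte-like cells 21.1% ± 4.64 and 22.1% ± 4.48 (SD, n = 3 each). Hormone-secreting enteroendocrine-like cells were more frequent in the libraries labelled Itgb7 KO, at 3.81% ± 0.54 against 2.52% ± 0.40 (SD, n = 3 each). The difference did not pass the adjusted test.

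For stem-like cells the log2 fold of the share was 0.02 ± 0.21 (SE) and for transit-amplifying-like cells −0.01 ± 0.16. It was 0.07 ± 0.19 for lower-villus and 0.07 ± 0.24 for mature enterocyte-like cells. Goblet-like cells, the mucus-producing class, here with the Atoh1-led cluster 0 included, took 20.2% ± 3.87 in wild-type libraries and 17.8% ± 7.04 in those labelled Itgb7 KO (SD, n = 3 each, log2 fold −0.19 ± 0.32, SE). Paneth-like cells, which secrete antimicrobial peptides at the crypt base, took 1.67% ± 1.88 and 1.29% ± 1.42 (SD, n = 3 each; log2 fold −0.38 ± 1.07, SE). All these shares had an edgeR adjusted p of 0.935. Paneth-like cells reached 3.84% in wild-type replicate 1 and 2.93% in the library labelled Itgb7 KO replicate 1, against 0.469% to 0.65% in the other 4 libraries. Those 2 libraries had the highest UMI minima (13621 and 7754, against 1417 to 2946). Without either one the Paneth-like log2 fold was 1.07 or −1.77. Goblet-like cells gave a log2 fold of −0.56 without the library labelled Itgb7 KO replicate 1.

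Enteroendocrine-like cells took 2.09%, 2.87% and 2.60% in the wild-type libraries and 3.26%, 3.81% and 4.35% in those labelled Itgb7 KO. Each of the latter lay above every wild-type library (exact 2-sided permutation test, p = 0.1). The log2 fold was 0.59 ± 0.20 (SE) and did not pass in edgeR (adjusted p = 0.192). With the replicate number as a block it was 0.59 ± 0.17 (SE) and did (edgeR adjusted p = 0.0229). Over all alternatives the edgeR adjusted p ran from 0.0229 to 0.95. The log2 fold ran from 0.22, with UMI minima matched between the groups in absolute UMIs, to 0.99, without correction for library. The class joined cluster 20, led by the progenitor gene Neurog3, and cluster 22, led by hormone genes. Cluster 22 took 1.26% ± 0.32 of wild-type cells and 2.44% ± 0.53 of those labelled Itgb7 KO (SD, n = 3 each; exact 2-sided permutation test, p = 0.1). Cluster 20 took 1.26% ± 0.13 and 1.37% ± 0.019 (SD, n = 3 each; exact 2-sided permutation test, p = 0.4). Tuft-like cells, the chemosensory class, took 0.359% ± 0.0993 and 0.488% ± 0.131 (SD, n = 3 each; log2 fold 0.49 ± 0.31, SE, edgeR adjusted p = 0.660). They numbered 42 wild-type cells and 63 labelled Itgb7 KO.

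**Figure D1:**
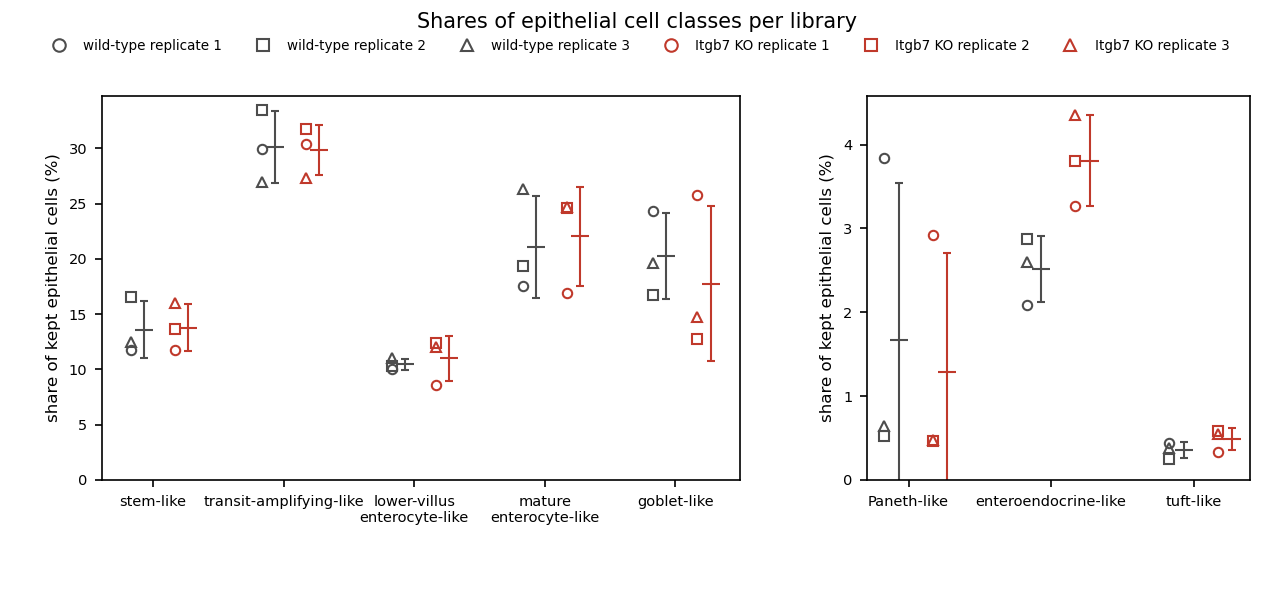
Share of each cell class among kept epithelial cells (y axis, %) in wild-type libraries (grey) and libraries labelled Itgb7 KO (red). Each symbol is 1 library, with its shape giving the replicate number, horizontal bars are means and error bars are SD (n = 3; the parts of the Paneth-like bars below 0% are not drawn), and the 3 libraries labelled Itgb7 KO lie at 3.26% to 4.35% enteroendocrine-like cells against 2.09% to 2.87% in wild-type.

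In stem-like and transit-amplifying-like cells, no gene of the Wnt and Notch pathways named here was called one by one in edgeR. These pathways set stem cell maintenance and the choice between absorptive and secretory fates. In stem-like cells the stem cell genes Lgr5 and Ascl2 had log2 fold changes of −0.26 ± 0.16 and −0.13 ± 0.17 (SE). The Notch target Hes1 had one of −0.07 ± 0.12 and the secretory fate genes Atoh1 and Dll1 of −0.10 ± 0.30 and 0.34 ± 0.25 (SE). The Wnt targets Axin2 and Sox9 stood at −0.09 ± 0.10 and −0.01 ± 0.11 (SE), and all 7 genes had an edgeR adjusted p of at least 0.964. In transit-amplifying-like cells Lgr5 had a log2 fold change of −0.34 ± 0.30, Axin2 of −0.29 ± 0.15 and Ascl2 of −0.38 ± 0.17 (SE). Sox9 stood at −0.07 ± 0.12, Hes1 at 0.08 ± 0.12, Atoh1 at −0.09 ± 0.29 and Dll1 at 0.33 ± 0.19 (SE), all with edgeR adjusted p values of at least 0.941. Some values depended on single libraries. Over the libraries left out in turn, Lgr5 ran from −0.70 to −0.08 in transit-amplifying-like cells and Atoh1 from −0.40 to 0.14 in stem-like cells.

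As a list, Wnt targets were lower in transit-amplifying-like cells labelled Itgb7 KO than other genes. Their median log2 fold change was −0.29, with a mean of −0.19 and 3 of 15 members positive (camera, adjusted p = 0.00754). The call was lost with an estimated correlation (adjusted p = 0.693) and in fry (adjusted p = 0.869). No member passed in edgeR, over all genes or adjusted over the list alone. It was also lost without wild-type replicate 2 (median −0.23, camera adjusted p = 0.104) and without the library labelled Itgb7 KO replicate 2 (median −0.08, camera adjusted p = 0.0970). In stem-like cells the Wnt list had a median of −0.09 (camera adjusted p = 0.360). Notch target and pathway genes had medians of −0.08 in stem-like (camera adjusted p = 0.243) and 0.00 in transit-amplifying-like cells (camera adjusted p = 0.261), the latter against a mean of −0.08. Both were called lower only without the library labelled Itgb7 KO replicate 3 (medians −0.17 and −0.17, camera adjusted p = 0.0442 and 0.0458). Secretory fate genes repressed by Notch had medians of −0.10 (camera adjusted p = 0.163) and −0.12 (camera adjusted p = 0.611) in the same classes. In stem-like cells their median was −0.40 without the library labelled Itgb7 KO replicate 2 (camera adjusted p = 0.0623). There they were called lower with 2 groups of serial numbers as a block (median −0.12, camera adjusted p = 0.0388).

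Across all genes, edgeR without a block called 1 transcript, Agpat4, which fell in the libraries labelled Itgb7 KO. Agpat4 (ENSMUSG00000023827, chromosome 17, positions 12118704 to 12219645, plus strand) encodes an acyltransferase of phosphatidic acid synthesis. It made 17.8, 17.6 and 15.3 CPM in wild-type libraries and 2.41, 2.38 and 1.90 in those labelled Itgb7 KO. The mean of the latter was 13.2% of the wild-type one. It fell by 3.15 on the log2 scale in stem-like cells (SE 0.25, edgeR adjusted p = 0.0124) and by 3.15 in lower-villus enterocyte-like cells (SE 0.24, edgeR adjusted p = 0.00537). It fell by 2.57 in goblet-like cells (SE 0.16, edgeR adjusted p = 0.0025) and fell by 3.002 in all epithelial cells (SE 0.21, edgeR adjusted p = 0.0139). Its log2 fold change was −3.02 ± 0.30 in transit-amplifying-like (edgeR adjusted p = 0.112), −3.52 ± 0.43 in mature enterocyte-like (edgeR adjusted p = 0.344) and −2.86 ± 0.55 in enteroendocrine-like cells (SE, edgeR adjusted p = 0.991). DESeq2 called it in all 6 of these classes. With the replicate number as a block edgeR also called it in transit-amplifying-like (adjusted p = 0.0247) and enteroendocrine-like cells (adjusted p = 0.0303). Agpat4 was named after its values were seen, since its level lay below the minimum of the naming rule. So was Mtus2 (chromosome 5, positions 147957320 to 148316065), which codes for a microtubule-associated protein. It made 4.75, 9.08 and 5.23 CPM in wild-type libraries and 0.804, 1.86 and 1.40 in those labelled Itgb7 KO, a mean of 21.4% of the wild-type one, with a log2 fold change of −2.31 ± 0.33 in all epithelial cells (SE, edgeR adjusted p = 0.517). DESeq2 called Mtus2 in 4 of the 6 classes in which it was tested. In edgeR it passed in enteroendocrine-like cells with the replicate block (−4.15 ± 0.73, SE, adjusted p = 0.0415) and in all epithelial cells with the serial numbers of the libraries as a block (−2.57 ± 0.20, SE, adjusted p = 0.00502). With that block it also passed in stem-like, transit-amplifying-like, goblet-like and enteroendocrine-like cells (edgeR adjusted p from 0.00448 to 0.0226).

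**Figure D2:**
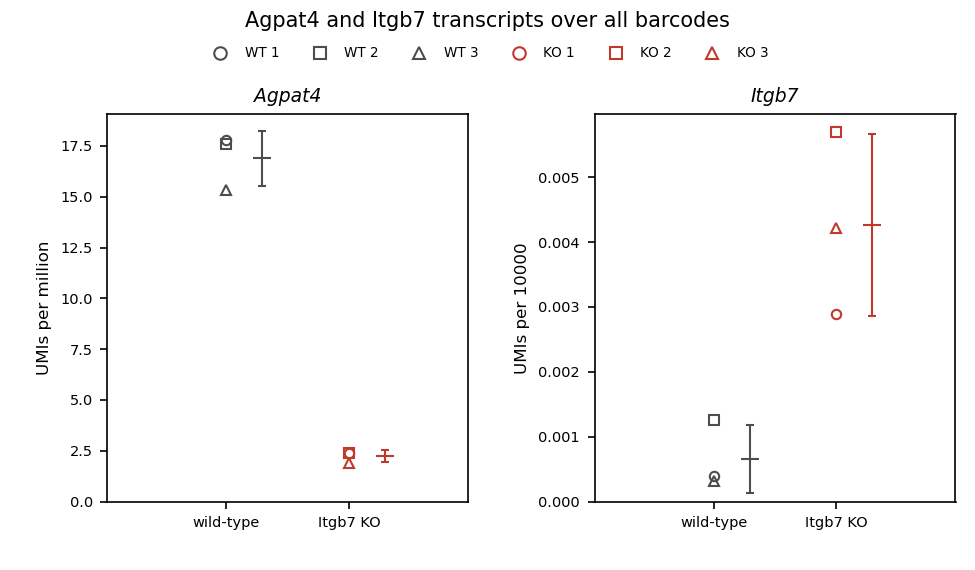
Agpat4 (y axis, counts per 1000000 UMIs, CPM) and Itgb7 (y axis, UMIs per 10000) over all barcodes of each library, wild-type in grey and labelled Itgb7 KO in red. Symbols are libraries with shapes for the replicate number, bars are means ± SD (n = 3), and Agpat4 lies at 1.90 to 2.41 CPM in the libraries labelled Itgb7 KO against 15.3 to 17.8 in wild-type.

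Without a block, Agpat4 was the 1 gene that edgeR called in stem-like (of 10784 tested), lower-villus enterocyte-like (of 9974), goblet-like (of 11091) and all epithelial cells (of 13540). DESeq2 called 6, 4, 13 and 25 genes in these groups, and 312, 363, 256 and 417 had an unadjusted edgeR p under 0.05. In transit-amplifying-like, mature enterocyte-like, Paneth-like and enteroendocrine-like cells edgeR called 0 of 11830, 10751, 2564 and 8427 genes, with 324, 427, 16 and 219 at an unadjusted p under 0.05, and DESeq2 called 10, 11, 1 and 3. With the replicate number as a block, edgeR called 1 gene in transit-amplifying-like, 2 in goblet-like, 2 in Paneth-like and 17 in enteroendocrine-like cells. With the serial numbers as a block it called between 4 genes in lower-villus enterocyte-like and 50 in enteroendocrine-like cells, and 0 in mature enterocyte-like cells (480 at an unadjusted p under 0.05). With 2 groups of serial numbers as a block, an alternative chosen after the data were seen, it called 11 genes in stem-like, 4 in transit-amplifying-like, 1 in lower-villus enterocyte-like, 5 in goblet-like and 3 in all epithelial cells. It then called 0 in mature enterocyte-like, Paneth-like and enteroendocrine-like cells (372, 23 and 186 at an unadjusted p under 0.05). Without a block, the calls in stem-like and all epithelial cells were lost (0 genes) without wild-type replicate 2 or the libraries labelled Itgb7 KO replicates 2 or 3, and in all epithelial cells also without wild-type replicate 3. The call was lost in lower-villus enterocyte-like cells without wild-type replicate 2 or the library labelled Itgb7 KO replicate 2. Over all libraries left out in turn, the log2 fold change of Agpat4 stayed between −3.31 and −2.97 in stem-like, −3.39 and −3.02 in lower-villus enterocyte-like and −3.15 and −2.85 in all epithelial cells (edgeR adjusted p up to 0.259, 0.146 and 0.291). Without the library labelled Itgb7 KO replicate 1, 2 genes were called in stem-like and 1 in transit-amplifying-like cells, and without wild-type replicate 3 edgeR called 3 in goblet-like cells.

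Camera called genes of antigen presentation and of the interferon response higher in the libraries labelled Itgb7 KO in every epithelial class in which they were tested. None of these calls held with an estimated correlation (adjusted p of at least 0.334), and the values of single libraries overlapped between the groups in some classes. MHC class II genes, which present extracellular antigens, had median log2 fold changes of 1.10 to 1.88 in 6 of 6 classes. Those of interferon response genes were 0.54 to 1.33 in 7 of 7 classes and those of MHC class I genes, which present intracellular antigens, 0.27 to 0.42 in 7 of 7. All 22 tested interferon response genes were positive in mature enterocyte-like cells (median 1.33), as were 24 of 25 in goblet-like cells (median 1.10). So were all 7 MHC class II genes in stem-like cells (median 1.52) and all 14 MHC class I genes in lower-villus enterocyte-like cells (median 0.42). Camera called each of these pairs of list and class, with adjusted p from 8.28e-28 for interferon response genes in goblet-like cells to 0.0479 for MHC class I genes in enteroendocrine-like cells.

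No call of the 3 lists held in fry (lowest adjusted p = 0.196) or with an estimated correlation. There the adjusted p ran from 0.693 to 0.747 for interferon response, from 0.693 to 0.747 for MHC class II and from 0.334 to 0.790 for MHC class I genes. Without a block no member passed over all genes tested in edgeR. DESeq2 called the interferon response genes Ddx60, Ifi27l2b, Ifi44, Ifit1, Isg15 and Oasl2 in goblet-like cells, H2-D1 and Igtp in mature enterocyte-like cells and Psmb9 and Ifit1 in all epithelial cells. It called Psmb8 in stem-like, transit-amplifying-like, both enterocyte-like and all epithelial cells. With the serial numbers as a block edgeR called 16 interferon response, 3 MHC class II and 2 MHC class I genes in goblet-like cells, and in stem-like cells H2-Aa, H2-Ab1, H2-DMa, H2-Eb1 and Psmb8. With 2 groups of serial numbers as a block these 5 genes were also called in stem-like cells, but in goblet-like cells only Ifitm3 of the interferon response list and 0 MHC class I or class II genes were. The planned serial block in effect left out wild-type replicate 3, which was alone in its block. Of the wild-type libraries, that one had the highest means of interferon response genes in stem-like and mature enterocyte-like cells. Adjusted over the list alone, 17 interferon response genes passed in goblet-like and 3 in lower-villus enterocyte-like cells. So did 7 MHC class II genes in stem-like and 6 in mature enterocyte-like cells, and 7 MHC class I genes in lower-villus enterocyte-like and 7 in transit-amplifying-like cells. Libraries differed within the groups too. In mature enterocyte-like cells the mean log2 CPM of MHC class II genes was 4.62, 1.32 and 3.73 in wild-type libraries and 6.08, 5.32 and 5.11 in those labelled Itgb7 KO. That of interferon response genes was 2.88, 2.75 and 3.13 in wild-type libraries and 4.95, 3.43 and 3.42 in those labelled Itgb7 KO. In stem-like cells it was 2.64, 2.64 and 3.06 against 3.89, 3.04 and 3.05. There, and in transit-amplifying-like and Paneth-like cells, the libraries labelled Itgb7 KO replicates 2 and 3 lay below wild-type replicate 3. The groups also overlapped for MHC class I genes in Paneth-like and enteroendocrine-like cells and for MHC class II genes in enteroendocrine-like cells.

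Several of these calls rested on single libraries. Without the library labelled Itgb7 KO replicate 1, interferon response genes were no longer called in Paneth-like (median 0.10, camera adjusted p = 0.663) and enteroendocrine-like cells (0.14, adjusted p = 0.566). Their medians were then 0.24 in stem-like, 0.26 in transit-amplifying-like, 0.38 in lower-villus enterocyte-like, 0.45 in mature enterocyte-like and 1.07 in goblet-like cells, where the call held. MHC class I genes then lost their call in Paneth-like (0.29, camera adjusted p = 0.276) and enteroendocrine-like cells (0.060, adjusted p = 0.563), and MHC class II genes in enteroendocrine-like cells (0.53, adjusted p = 0.0570). In Paneth-like cells the interferon call was also lost without wild-type replicate 2 or 3 (camera adjusted p = 0.121 and 0.0541). The MHC class I call was lost there without wild-type replicate 1 or the library labelled Itgb7 KO replicate 2 (camera adjusted p = 0.0896 and 0.148). In enteroendocrine-like cells the MHC class I call was also lost without wild-type replicates 2 or 3 or the library labelled Itgb7 KO replicate 2 (camera adjusted p = 0.398, 0.145 and 0.0735). With only the 4 libraries of replicates 2 and 3, interferon response genes were called in 4 classes. Markers of B, T and myeloid cells pooled made 9.45 ± 1.27 (SD, n = 3) CPM in wild-type libraries and 7.46 ± 1.27 (SD, n = 3) in those labelled Itgb7 KO. The 3 lists were singled out after the list tests were seen.

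**Figure D3:**
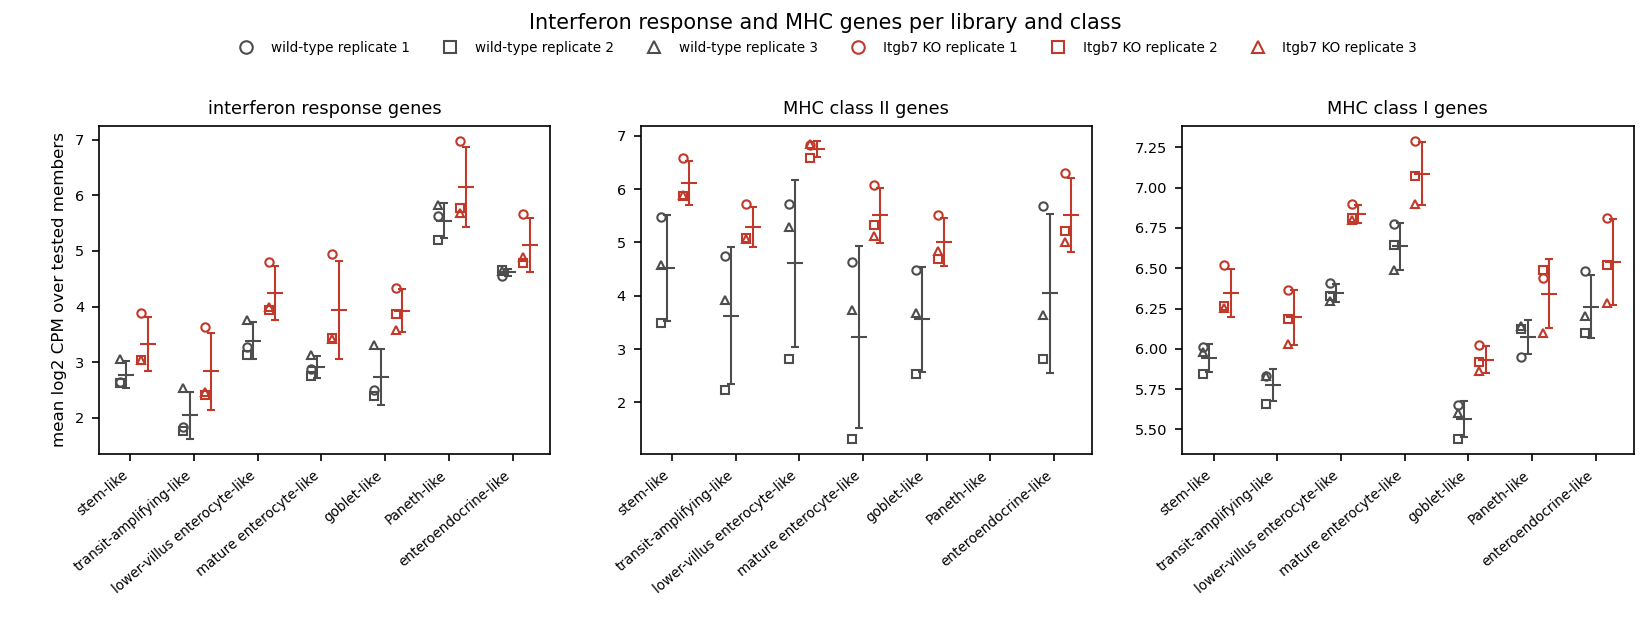
Mean log2 CPM (y axis, counts per 1000000 UMIs) over the tested members of 3 gene lists in each epithelial class, for wild-type libraries (grey) and libraries labelled Itgb7 KO (red). Symbols are libraries with shapes for the replicate number, horizontal bars are means and error bars are SD (n = 3); MHC class II genes were not tested in Paneth-like cells, and in mature enterocyte-like cells they lie at 5.11 to 6.08 in the libraries labelled Itgb7 KO against 1.32 to 4.62 in wild-type.

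The list members with the smallest unadjusted p all came from these lists in lower-villus enterocyte-like, mature enterocyte-like and goblet-like cells. In enteroendocrine-like cells none did, and in the remaining groups only some. None of these members passed in edgeR without a block. Psmb8, a subunit of the immunoproteasome that prepares peptides for MHC class I, had log2 fold changes of 0.88 ± 0.18 in stem-like, 0.95 ± 0.20 in transit-amplifying-like, 1.01 ± 0.17 in lower-villus enterocyte-like and 0.98 ± 0.20 in mature enterocyte-like cells (SE; edgeR adjusted p from 0.791 to 0.964). In all epithelial cells it averaged 126 ± 23.2 and 244 ± 27.9 CPM (SD, n = 3 each; log2 fold change 0.95 ± 0.17, edgeR adjusted p = 0.764). Psmb9 stood there at 0.54 ± 0.11, the cell-cycle inhibitor Cdkn1c at 0.83 ± 0.18 and Ifit1 at 1.62 ± 0.40 (SE). In lower-villus enterocyte-like cells the peptide transporter Tap1 stood at 0.89 ± 0.18, Psmb9 at 0.61 ± 0.13 and H2-DMa, which loads MHC class II, at 1.16 ± 0.27 (SE). H2-DMa stood at 1.27 ± 0.32 (SE) in stem-like cells. Mature enterocyte-like cells gave H2-D1 at 0.57 ± 0.14, H2-T23 at 0.81 ± 0.20 and the interferon-induced GTPase Igtp at 2.22 ± 0.59 (SE). In goblet-like cells Ddx60 stood at 1.68 ± 0.24, Ifit1 at 2.65 ± 0.44, Ifi27l2b at 0.93 ± 0.17 and Isg15, an interferon-induced ubiquitin-like protein, at 1.88 ± 0.35 (SE; edgeR adjusted p from 0.407 to 0.956). With the serial numbers as a block edgeR called Psmb8 in stem-like (adjusted p = 0.0205), transit-amplifying-like (0.0296), lower-villus enterocyte-like (0.0488) and all epithelial cells (0.0473), and H2-DMa in stem-like cells (0.0205). In goblet-like cells that fit called Ddx60, Ifit1, Ifi27l2b and Isg15 (edgeR adjusted p from 0.000558 to 0.00681). With 2 groups of serial numbers as a block edgeR called none of these 4 in goblet-like cells. It called Psmb8 then in stem-like (adjusted p = 0.0268) and transit-amplifying-like (0.0288) but not in lower-villus enterocyte-like or all epithelial cells, H2-DMa in stem-like (0.0268) and Igtp in transit-amplifying-like cells (0.0282).

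The other members named came from the stress, clock, cell-cycle, MHC, unfolded protein response and mitochondrially encoded lists. In stem-like cells the stress-response factor Atf3 had a log2 fold change of −0.95 ± 0.14 (SE, edgeR adjusted p = 0.492) and the clock gene Nr1d1 of −1.12 ± 0.28. Transit-amplifying-like cells gave Psmb9 at 0.55 ± 0.13, the endoplasmic reticulum protein Sdf2l1 at 0.44 ± 0.11 and the immediate early gene Fosb at −0.51 ± 0.14 (SE, each with edgeR adjusted p = 0.941). Enteroendocrine-like cells gave the chaperones Dnajb1 at 1.07 ± 0.29 and Hspa1a at 2.23 ± 0.67, the cytokine signalling inhibitor Socs3 at 1.30 ± 0.41 and the cell-cycle inhibitor Cdkn1a at 0.95 ± 0.32 (SE, each with edgeR adjusted p = 0.991). Paneth-like cells gave the stress gene Ddit3 at 1.26 ± 0.34, the MHC class II genes H2-Ab1 and Cd74 at 1.07 ± 0.36 and 0.90 ± 0.33, and mt-Atp8 at −0.80 ± 0.27 (SE, each with edgeR adjusted p = 0.999). With the replicate number as a block Ddit3 passed in Paneth-like cells (edgeR adjusted p = 0.0243). With the serial numbers as a block edgeR called Atf3 in stem-like (adjusted p = 0.0314), Cdkn1a in enteroendocrine-like (0.0151) and Ddit3, H2-Ab1 and Cd74 in Paneth-like cells (0.0453, 0.0453 and 0.0341). Of these, Atf3 alone was also called with 2 groups of serial numbers as a block (0.0413).

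Camera also called other lists, and each of these calls was lost with an estimated correlation and in fry. Ribosomal protein genes were called lower in 7 of 7 classes (medians −0.42 to −0.17; adjusted p from 0.790 to 0.829 with an estimated correlation). In each class the library labelled Itgb7 KO replicate 1 lay within the range of the wild-type libraries, at 11.08 in stem-like cells against 10.86 to 11.10 (mean log2 CPM), and in Paneth-like cells so did replicate 3 of its group. The ribosomal call was lost in stem-like and Paneth-like cells without the library labelled Itgb7 KO replicate 2 (camera adjusted p = 0.0836 and 0.128) and in Paneth-like cells also without wild-type replicate 3 (0.123). Goblet cell products such as Muc2 were called lower in 5 classes other than goblet-like cells (stem-like −0.60, transit-amplifying-like −0.59, lower-villus enterocyte-like −0.66, mature enterocyte-like −0.63, enteroendocrine-like −0.69). The adjusted p of these calls ran from 0.790 to 0.845 with an estimated correlation. All 5 were lost without wild-type replicate 1 (camera adjusted p from 0.178 to 0.855), and those in mature enterocyte-like and enteroendocrine-like cells also without the library labelled Itgb7 KO replicate 3 (0.0646 and 0.196). Goblet-like cells themselves had been 20.2% of wild-type and 17.8% of cells labelled Itgb7 KO. In enteroendocrine-like cells DNA replication genes were called lower (−0.42, 0 of 21 positive) and cell-cycle inhibitors higher (0.43, 11 of 11 positive), with adjusted p of 0.790 and 0.693 with an estimated correlation. Immediate early and heat-shock genes were also called higher there (0.61; adjusted p = 0.747 with an estimated correlation). These 3 calls held whichever library was left out (camera adjusted p up to 0.0315, 0.0109 and 0.000186). Hormone cluster 22 made up more of this class in the libraries labelled Itgb7 KO than in wild-type ones.

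Each of the following list calls was lost without at least 1 library, named beside it. Proximal intestine genes were called higher in 4 classes (transit-amplifying-like 0.14, lower-villus enterocyte-like 0.30, mature enterocyte-like 0.21, enteroendocrine-like 0.45; adjusted p = 0.693 with an estimated correlation). All 4 calls were lost without the library labelled Itgb7 KO replicate 2 (camera adjusted p from 0.0637 to 0.142) and, except in lower-villus enterocyte-like cells, without replicate 1 of that group (0.0953 to 0.167). They were also lost without wild-type replicate 2 in transit-amplifying-like and enteroendocrine-like and without wild-type replicate 3 in mature enterocyte-like cells (0.176, 0.107 and 0.333). Xenobiotic metabolism genes were called higher in lower-villus enterocyte-like cells (0.21), but not without wild-type replicate 3 or the libraries labelled Itgb7 KO replicates 1 or 3 (medians from 0.11 to 0.36 over the libraries left out). In mature enterocyte-like cells they were called higher (0.29), but not without wild-type replicate 3 (0.10 to 0.54; adjusted p = 0.790 with an estimated correlation). Fatty acid oxidation genes were called higher in transit-amplifying-like cells (0.16), but not without wild-type replicates 1 or 3 or the libraries labelled Itgb7 KO replicates 1 or 2 (0.065 to 0.22). The same list was called higher in mature enterocyte-like cells (0.21), but not without wild-type replicate 3 or the libraries labelled Itgb7 KO replicates 1 or 2 (0.071 to 0.33; adjusted p = 0.790 with an estimated correlation).

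Unfolded protein response genes were called higher in transit-amplifying-like cells (0.07), but without wild-type replicates 2 or 3 or the libraries labelled Itgb7 KO replicates 1 or 2 they were not (−0.0052 to 0.17). Their call in Paneth-like cells (0.21) was lost without wild-type replicates 1 or 3 or the library labelled Itgb7 KO replicate 2 (−0.044 to 0.32; adjusted p = 0.790 with an estimated correlation). Immediate early and heat-shock genes were called lower in stem-like cells (−0.16), but not without wild-type replicate 2 or the library labelled Itgb7 KO replicate 1 (−0.27 to −0.057). They were called higher in goblet-like cells (0.22), but not without wild-type replicates 1 or 3 or the library labelled Itgb7 KO replicate 3 (0.12 to 0.41), and in Paneth-like cells (0.16), but not without wild-type replicate 1 (0.17 to 0.35; adjusted p from 0.747 to 0.845 with an estimated correlation). The stem cell signature was called lower in enteroendocrine-like cells (−0.22), but not without the library labelled Itgb7 KO replicate 1 (−0.44 to −0.28). Its call in mature enterocyte-like cells (−0.22) was lost without wild-type replicate 3 or the library labelled Itgb7 KO replicate 1 (−0.30 to −0.020; adjusted p from 0.693 to 0.790 with an estimated correlation). Oxidative phosphorylation genes were called higher in lower-villus enterocyte-like cells (0.08), but not without wild-type replicates 2 or 3 or the library labelled Itgb7 KO replicate 1 (0.052 to 0.11). In enteroendocrine-like cells they were called lower (−0.19), but not without wild-type replicate 1 or the libraries labelled Itgb7 KO replicates 2 or 3 (−0.34 to 0.049; adjusted p from 0.790 to 0.881 with an estimated correlation).

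In lower-villus enterocyte-like cells secretory fate genes were called lower (−0.54), but not without wild-type replicate 3 or the library labelled Itgb7 KO replicate 1 (−0.61 to −0.34). Cholesterol synthesis genes were called lower there (−0.21), but not without the library labelled Itgb7 KO replicate 3 (−0.32 to −0.052). So were mitosis genes (−0.16), but not without wild-type replicates 1 or 3 or the libraries labelled Itgb7 KO replicates 2 or 3 (−0.30 to −0.057). Type 2 immunity genes were called higher there (0.34, with 3 members adjusted over the list alone), but not without wild-type replicate 2 or the library labelled Itgb7 KO replicate 1 (0.19 to 0.32). These 4 lists had an adjusted p from 0.693 to 0.868 with an estimated correlation. Clock genes were called lower in transit-amplifying-like cells (−0.13), but not without wild-type replicate 2 or any one of the libraries labelled Itgb7 KO (−0.34 to 0.013). Regeneration genes were called lower in stem-like cells (−0.58 over 3 members), but not without wild-type replicate 2 or the library labelled Itgb7 KO replicate 1 (−0.85 to −0.43). Both had an adjusted p of 0.693 with an estimated correlation.

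In all, camera called 59 of the 213 pairs of list and class. The mean had the sign of the median in every called pair. None of the 59 held with an estimated correlation (lowest adjusted p = 0.334) or in fry (lowest adjusted p = 0.196). Of the 59, 47, 48 and 44 were still called in the same direction without wild-type replicates 1, 2 and 3, and 39, 43 and 51 without the libraries labelled Itgb7 KO replicates 1, 2 and 3. With the replicate number as a block all 59 kept their call and direction and 19 others were called. With the serial numbers as a block 48 kept both and 21 others were called, and with 2 groups of serial numbers 51 and 26. Both serial blocks lost the calls of fatty acid oxidation genes, of xenobiotic metabolism and mitosis genes in lower-villus enterocyte-like, of immediate early genes in goblet-like and of unfolded protein response genes in Paneth-like cells. The serial numbers as a block also lost those of secretory fate and oxidative phosphorylation genes in lower-villus enterocyte-like cells and of the stem cell signature, xenobiotic metabolism and proximal intestine genes in mature enterocyte-like cells. The 2 groups of serial numbers lost those of goblet cell products and oxidative phosphorylation genes in enteroendocrine-like cells.

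Without a block no member of any tested list passed in edgeR over all genes. The replicate block called Ddit3 in Paneth-like and Sct, Fabp6 and H2-Q2 in enteroendocrine-like cells. Ly6a, of the regeneration list, was called in goblet-like cells by DESeq2 and with both serial blocks. Of 33 lists tested 12 were called in no class without a block. Among them Paneth cell products were called lower in 4 classes with the replicate block (medians from −0.92 in lower-villus enterocyte-like to −0.48 in stem-like cells) and in 5 with the serial block (−0.72 to −0.36). With 2 groups of serial numbers as a block the list was called in goblet-like cells alone, and higher (0.15, camera adjusted p = 0.0340). Distal intestine genes were called lower in 3 classes with the replicate block (−0.18 in stem-like, transit-amplifying-like and lower-villus enterocyte-like cells), in 2 with the serial block and in 0 with 2 groups of serial numbers. Antimicrobial and barrier genes were called higher in 7 of 7 classes with 2 groups of serial numbers as a block (medians 0.0012 to 0.37, camera adjusted p from 6.68e-05 to 0.0237), in 0 with the replicate block and in stem-like and goblet-like cells with the serial block (0.19 and 0.021). Notch pathway, adherens junction and endocytosis genes were called in 0 classes without a block and with each of the 3 blocks. Over all barcodes, those of Paneth-like cells included, Paneth cell products made 58905 and 37512 CPM in replicate 1 of the wild-type and labelled Itgb7 KO groups. They made 2619 to 3234 CPM in the other libraries. How much of this was free RNA was not tested. Erythrocyte and T cell transcripts had too few expressed members to be tested as lists. T cell effector genes were fixed for T-cell-like clusters, of which there were none, and sex-linked and strain background genes were not tested as lists.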

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

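The tests of T cell RNA, of exchanged labels, of library batches, of intestinal region (in every form), of matched UMI minima and of the other splits for numbers of genes were chosen only after the result was seen.

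Transcripts of cell types that the comparisons do not use exceeded the highest wild-type library with more than 3 UMIs in 3 places. Erythroid transcripts made 5.16 CPM in the library labelled Itgb7 KO replicate 1, where Hbb-bs had 188 UMIs in 12 barcodes, and 0.0863 CPM in replicate 2 of that group, against at most 0.0474 in wild-type libraries. In replicate 3 of that group 2 erythroid UMIs, below that minimum, made 0.0702 CPM. B or plasma cell transcripts made 3.28 CPM in the library labelled Itgb7 KO replicate 1, against 2.29 to 2.78 in wild-type libraries.

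Itgb7 UMIs were 6.49 times as frequent in the libraries labelled Itgb7 KO as in wild-type libraries. Free RNA from T cells is argued against as far as the pooled markers stand for T cells, because they were lower in the libraries labelled Itgb7 KO (log2 ratio −0.90). They made 1.19 to 1.83 CPM there against 1.96 to 4.12 in wild-type libraries, the highest in wild-type replicate 1. The most abundant of these markers were Lck, Ptprcap and Ccl5. Wild-type replicates 2 and 3 held 124 and 166 UMIs of the pool but 0 of Ccl5, so part of the pool may come from other cells. A segment of another strain around the gene is argued against as far as it would change expression nearby, because the median absolute log2 fold change of 105 genes within 5 Mb lay at the 16.1 percentile of 10000 random sets of the same size and level. An exchange of the labels of both groups cannot be told apart from a transcript that persists in the mutant, since all 6 libraries lay on the other group's side and the deleted part is not stated. A mutant transcript that is kept or made more often, the biological explanation the design gives, may apply and was not tested.

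Camera called interferon response and MHC genes higher in the libraries labelled Itgb7 KO in every class tested (median over lists and classes 0.85, log2) but in 0 classes with an estimated correlation (lowest adjusted p = 0.334) or in fry (0.196), and for interferon response genes replicates 2 and 3 of that group lay below wild-type replicate 3 in stem-like, transit-amplifying-like and Paneth-like cells. With 2 groups of serial numbers as a block this median was 1.04 and with the planned serial block 1.05. The difference did not fall, which argues against a shift shared by each serial group as its source. In the planned serial block, however, wild-type replicate 3 was alone, so that median rests on the other libraries. In both forms of the block wild-type replicate 2 and the library labelled Itgb7 KO replicate 1 were each alone for their label in their serial group. The blocked values rest largely on them, and the labels do not call these numbers batches, so other library batches stay open. Free RNA from immune cells is argued against as far as the markers stand for such cells, because pooled B, myeloid and T cell markers had a log2 ratio of −0.34 (B or plasma cell markers alone 0.05). The most abundant were Cd68, Cd79b and Lck, and how much of the pool came from other cells was not tested. A different mix of intestinal regions stays open, because the test did not hold region fixed: within enterocyte clusters led by distal or by proximal genes the effect was at least 0.961 of that in all enterocytes (a first form of the test gave 1.09 and 1.12), but proximal intestine genes were also higher there in the libraries labelled Itgb7 KO by 0.33 and 0.28 (log2), against 0.30 in all enterocytes. The wild-type difference between proximal-led and distal-led clusters was −2.01 ± 0.13 for MHC class II, 0.43 ± 0.26 for interferon response and 0.35 ± 0.093 for MHC class I genes (SD, n = 3 each). But the proximal-led clusters were mature enterocyte-like. The only distal-led one, cluster 1, was named lower-villus enterocyte-like on 3 markers against 2 of mature enterocytes, so region and maturation were mixed. An effect of the genotype may apply, but so may housing, microbiota or infection, on which the labels say nothing, so no cause was identified.

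Enteroendocrine-like cells took a larger share in the libraries labelled Itgb7 KO, with a log2 fold of 0.59. The UMI minima of the libraries stay open, because with minima matched relative to each library's median the log2 fold was 0.49 ± 0.31 (SE), above the bound that would have spoken against them by less than its SE, and in replicate 1 the shares then were 2.09% and 2.12%. A different mix of intestinal regions stays open too. Within the class the median log2 fold change was 0.96 for hormone genes of the proximal gut and 0.56 for those of the distal gut. The difference of 0.40 lay between the bounds set for a yes and a no. Genotype and both technical explanations may contribute and cannot be told apart here.

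The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1 gene in stem-like cells, and 2 of the 10 splits called as many (highest other 491). As many as the 1 gene in lower-villus enterocyte-like cells were called in 2 splits (highest other 304), in goblet-like cells in 2 (highest other 453) and in all epithelial cells in 2 (highest other 425). Where edgeR called 0 genes, all 10 splits called as many, with a highest other of 636 in transit-amplifying-like, 10 in mature enterocyte-like, 3 in Paneth-like and 0 in enteroendocrine-like cells, where 324, 427, 16 and 219 genes had an unadjusted p under 0.05 in the real split and DESeq2 called 10, 11, 1 and 3. The split of wild-type replicates 1 and 3 with the library labelled Itgb7 KO replicate 1 gave the highest other count in each of these groups except Paneth-like and enteroendocrine-like cells. The many genes it called point to a structure of the samples apart from genotype. This split parts 1 planned group of serial numbers in the deposited file names from all other libraries. Those were joined into 1 group only after the data were seen, so the match is no independent sign that the serial numbers mark this structure. With these 2 serial groups as a block edgeR called 11 genes for genotype in stem-like, 4 in transit-amplifying-like, 1 in lower-villus enterocyte-like, 5 in goblet-like and 3 in all epithelial cells, and 0 in mature enterocyte-like, Paneth-like and enteroendocrine-like cells (372, 23 and 186 at an unadjusted p under 0.05).

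Interferon response genes were called in 7 classes by 3 of the 10 splits (highest other 7), MHC class II genes in 6 classes by 4 (highest other 6) and MHC class I genes in 7 classes by 2 (highest other 7), while the serial split called each of these lists in 0 classes. Of the 10 splits, 4 part every replicate pair as the real one does. The other 3 of these called 0 genes in each class and in all epithelial cells with edgeR (7 to 224 at an unadjusted p under 0.05, with 131, 132 and 139 in stem-like cells; DESeq2 was not run on other splits). They called interferon response, MHC class II and MHC class I genes in 7, 5 and 7 classes, in 5, 0 and 2, and in 1, 6 and 0. For each list taken singly, their highest count (7, 6 and 7) equalled that of the real split, though none of them reached all 3 counts at once. These 4 splits are too few for a share under 0.05. Over all lists these 3 splits called 50, 50 and 25 of the 213 pairs, against 59 in the real split, and of the other 6 splits 4 called more (60, 70, 79 and 92).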

How the results depend on the processing

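The blocks of 2 serial groups, the 4 libraries, the matched UMI minima and all alternatives of the interferon and MHC lists were chosen only after the results were seen. The main camera tests of these lists were planned, but their result was singled out after the list tests were seen. Numbers of genes called, in the order stem-like, transit-amplifying-like, lower-villus enterocyte-like, mature enterocyte-like, goblet-like, Paneth-like, enteroendocrine-like and all epithelial cells (1, 0, 1, 0, 1, 0, 0 and 1 in edgeR, with 312, 324, 363, 427, 256, 16, 219 and 417 at an unadjusted p under 0.05), were 6, 10, 4, 11, 13, 1, 3 and 25 in DESeq2. Only counts that moved are given from here, and the cause was not tested unless stated. The serial block gave 12, 5, 4, 46, 8, 50 and 7 in stem-like, transit-amplifying-like, lower-villus enterocyte-like, goblet-like, Paneth-like, enteroendocrine-like and all epithelial cells, and the 2 serial groups 11, 4, 5 and 3 in stem-like, transit-amplifying-like, goblet-like and all epithelial cells. The replicate block gave 1 in transit-amplifying-like, 2 in goblet-like, 2 in Paneth-like and 17 in enteroendocrine-like cells. Without the filter on low counts 3, 3, 1, 3, 8 and 3 genes were called in transit-amplifying-like, lower-villus, mature enterocyte-like, goblet-like, Paneth-like and enteroendocrine-like cells. The 4 libraries of replicates 2 and 3 gave 2, 1, 10, 17, 31 and 19 in stem-like, transit-amplifying-like, lower-villus, goblet-like, enteroendocrine-like and all epithelial cells. With 1 UMI minimum edgeR called 0 in stem-like, lower-villus, goblet-like and all epithelial cells, in fits of 5 libraries: the library labelled Itgb7 KO replicate 3 kept 2 stem-like, 3 lower-villus and 2 goblet-like cells and dropped out. Leiden resolution 2.5 gave 0 in stem-like and 1 in mature enterocyte-like cells, and thinning 1 in transit-amplifying-like and 0 in goblet-like cells. No correction for library gave 0 in lower-villus cells and 4 in stem-like cells, the latter in a fit of 4 libraries, because wild-type replicate 1 held 0 and the library labelled Itgb7 KO replicate 1 held 2 stem-like cells. Paneth-like and enteroendocrine-like cells were too few for a gene test with 1 UMI minimum.

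Leaving out each library in turn gave 0 to 2 genes in stem-like, 0 to 1 in transit-amplifying-like, lower-villus and all epithelial, 0 to 0 in mature enterocyte-like, Paneth-like and enteroendocrine-like and 1 to 3 in goblet-like cells. Log2 folds of shares then ran from −0.10 to 0.19 (stem-like), −0.09 to 0.07 (transit-amplifying-like), −0.02 to 0.22 (lower-villus), −0.05 to 0.26 (mature enterocyte-like), −0.56 to 0.0016 (goblet-like), −1.77 to 1.07 (Paneth-like), 0.48 to 0.70 (enteroendocrine-like) and 0.27 to 0.68 (tuft-like). Medians of Wnt targets ran from −0.14 to −0.04 in stem-like and −0.38 to −0.080 in transit-amplifying-like cells, of Notch pathway genes from −0.17 to −0.066 and −0.17 to 0.033, and of secretory fate genes from −0.40 to −0.029 and −0.22 to −0.06. Interferon response, MHC class II and MHC class I genes were called in 5 to 7, 6 to 7 and 5 to 7 classes, and the Itgb7 log2 fold change ran from 2.78 to 3.53.

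With 1 UMI minimum the log2 fold of the stem-like share was −0.21 and of the transit-amplifying-like share 0.17, with 2 and 8 such cells in the library labelled Itgb7 KO replicate 3. The enteroendocrine-like share passed with the replicate block (0.59, adjusted p = 0.0229) and otherwise moved to 0.91 with doublets kept, 0.92 at 10% mitochondrial UMIs, 0.80 at resolution 2.5, 0.99 without correction for library and 0.22 with absolute matched minima, with an adjusted p from 0.0229 to 0.95 over all alternatives, and the tuft-like share was 0.84 in the 4 libraries. Wnt targets in stem-like cells were called lower with doublets kept (−0.20, adjusted p = 0.0364) and at resolution 2.5 (−0.13, adjusted p = 0.0418), as were secretory fate genes with 2 serial groups as a block (−0.12, adjusted p = 0.0388), under which Notch genes in transit-amplifying-like cells moved to −0.16. The Wnt call in transit-amplifying-like cells was lost with an estimated correlation (adjusted p = 0.693) and in fry (adjusted p = 0.869), against 0.00146 to 0.869 over all alternatives. Interferon response genes were called in 4 classes in the 4 libraries, and all 3 lists in 0 classes with an estimated correlation and in fry. Itgb7 was called in DESeq2 (3.22, adjusted p = 0.0229) and had a log2 fold change of 2.65 with doublets kept. The cause was not tested for these changes. The replicate block changed the call of no other share, of no Wnt, Notch or secretory list in these classes and of no interferon or MHC list.

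None of the shares, integrins and named genes turned direction past a threshold, nor did the Wnt, Notch and secretory fate lists in stem-like and transit-amplifying-like cells. The other lists were not part of this check. Among them, Paneth cell products were called lower in 4 classes with the replicate block, but higher in goblet-like cells with 2 serial groups as a block. Of the values of single named genes under alternatives, 660 were the same, 59 were stronger, 9 were weaker and 27 moved. Depth limits the library labelled Itgb7 KO replicate 3 most (28475253 UMIs, median 6079.5 per barcode), and in enteroendocrine-like cells only 8% of simulated 2-fold changes were recovered.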

Other observations

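The genes in this part were chosen after their values were seen, and so was the block of 2 serial groups.

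Within enteroendocrine-like cells, 11 hormone and marker genes were examined, and their log2 fold changes were all positive. These differences within the class came with its shift of clusters, since hormone cluster 22 took 1.26% of wild-type cells and 2.44% of those labelled Itgb7 KO and progenitor cluster 20 took 1.26% and 1.37%. The clusters were not tested apart. Ghrl, which encodes the appetite hormone ghrelin, averaged 1630 ± 768 CPM in wild-type libraries and 5130 ± 878 in those labelled Itgb7 KO (SD, n = 3 each), a log2 fold change of 1.66 ± 0.38 (SE), which edgeR did not call without a block (adjusted p = 0.991) and DESeq2 did (adjusted p = 0.0196). The granule protein gene Chga stood at 1.15 ± 0.37, Cck at 1.04 ± 0.64, secretin (Sct) at 0.88 ± 0.55 and Gip at 0.58 ± 0.63 (SE, edgeR adjusted p = 0.991 each). With the replicate number as a block edgeR called Ghrl (1.76, adjusted p = 0.0246), Chga (1.17, adjusted p = 0.0276), Sct (1.05, adjusted p = 0.0303) and Cpe (1.31, adjusted p = 0.00899). With the serial block it called the same 4 genes (adjusted p from 0.000389 to 0.0120). With 2 serial groups as a block edgeR called 0 genes in this class (186 at an unadjusted p under 0.05), and without a block DESeq2 called 3. Neurog3, the transcription factor of enteroendocrine progenitors, stood at 0.02 ± 0.48 (SE). Over all epithelial cells DESeq2 also called Ghrl (1.79), the prohormone processing genes Pcsk1n (1.16), Cpe (1.45) and Scg5 (1.22), and Pdx1 (0.95), a transcription factor of the pancreas and duodenum. There edgeR called none of these 5 genes without a block or with the replicate block, and Ghrl with the serial block (2.04, adjusted p = 0.00502) and with 2 serial groups as a block (1.92, adjusted p = 0.0327).

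Other genes that DESeq2 called, and edgeR without a block did not, included interferon-induced genes that the fixed lists did not hold. Ifi47, an interferon-induced GTPase, had DESeq2 log2 fold changes of 0.88 in transit-amplifying-like, 1.27 in lower-villus enterocyte-like, 1.21 in mature enterocyte-like and 1.51 in goblet-like cells. In goblet-like cells edgeR called it with the replicate block (1.51, adjusted p = 0.0352) and with the serial block (1.63, adjusted p = 0.00829), but not with 2 serial groups as a block. Iigp1, of the same family, stood at 3.18 in transit-amplifying-like cells. In stem-like cells DESeq2 called Atf3 (−0.94), Nr4a1 (−1.19) and the growth factor gene Hbegf (−0.88) lower. So did edgeR with the serial block (adjusted p = 0.0314, 0.0337 and 0.0294) and with 2 serial groups as a block (adjusted p = 0.0413, 0.0436 and 0.0300).

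Wild-type replicate 1 held 126 UMIs of the T cell chemokine gene Ccl5 in 122 barcodes and 47 of Gzma in 46. Ccl5 had 3 and 1 UMIs in the libraries labelled Itgb7 KO replicates 1 and 2, Gzma had 1 in wild-type replicate 2, and the other libraries held 0 of either. Pancreatic acinar transcripts made 664 CPM in wild-type replicate 1 and 450 in the library labelled Itgb7 KO replicate 1, against 36.6 to 45.6 in the other libraries. Nnt, which is mutated in the C57BL/6J strain, made 27.9, 34.4 and 26.5 CPM in wild-type libraries and 21.0, 39.2 and 52.3 in those labelled Itgb7 KO.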
